A study of Bos taurus with 18 samples.

How the data were processed

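Before the data were examined, the comparisons, the unit of replication, the alternatives to be tried and the gene lists were set down. The calf was the unit: each γδ minus αβ or 48 h minus 0 h difference was formed within a calf, so that differences between calves in extraction and amplification dropped out as far as they were constant. What had to be settled from the values themselves was the scale of 3 arrays, the normalization and the gene-level filter.

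Per the labels, cells came from lymphatic fluid and were sorted with a fluorescein-labelled γδ T cell antibody. RNA of calves 156 and 162 was taken with a column kit and labelled in 1 cycle, that of calf 112 with TRIzol and labelled in 2 cycles. The authors hybridized 15 µg of fragmented cRNA to each array and obtained intensity values with GCOS. How the αβ fraction was gated, and which summarisation setting was used, is not given in the sources used here.

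The deposited intensity values covered 24128 probe sets, 112 of them controls. On 15 arrays the mean between percentiles 2 and 98 was within 10 percent of 500. On the other 3, the γδ arrays of calf 112 at 6, 24 and 72 h, it was 27.1, 41.0 and 37.4, and these arrays were multiplied by 18.4, 12.2 and 13.4 to reach 500. A constant of 32 was added and log2 taken. The quartiles then differed between arrays by more than 0.1, from 5.88 to 6.35 for the lower, 7.19 to 7.63 for the median and 8.91 to 9.30 for the upper quartile, so quantile normalization was applied. A probe set was kept if it lay above percentile 60 of its array on at least 2 arrays, which left 13790.

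Names came from the probe annotation of the reference tables. It gave 1 symbol to 13318 probe sets, several to 86 and none to 10724, and probe sets with several symbols were not named. The kept probe sets with 1 symbol covered 6661 symbols, and a gene in a list was represented by its brightest probe set.

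Tests used limma with a trended variance prior on the within-calf differences, and p values were adjusted by the Benjamini-Hochberg method over the kept probe sets. A probe set was called at an adjusted p below 0.05. The γδ and αβ cells were compared on 3 calves, and the 48 h change in the infected calves was tested on 2 calves. The spread of those 2 calves gave 1 residual degree of freedom before moderation. The prior from all kept probe sets added 7.67 degrees of freedom in αβ and 9.69 in γδ cells, so it set most of the variance. The infected minus mock comparison set 2 calves against 1 and took its variance in the same way. For the γδ minus αβ change the prior added 23.3. SE values below are these moderated ones and can be smaller than the spread between the 2 calves. Where fewer than 6 named genes passed in a direction, genes at least 2-fold in both infected calves and not in the mock calf were added, ranked by the smaller of their changes in the infected calves, as values and not as calls. Fold changes within 1 calf were counted without a test, beside the number expected if calves or cell types were independent.

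Gene lists were tested with camera at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. At the preset correlation p values set the list's genes against other genes and do not measure the spread of a list between calves. With an estimated correlation camera keeps only the residual degrees of freedom, 2 for γδ against αβ cells and 1 elsewhere. A list can then hardly pass, so that losses at this setting say little about the correlation of its genes. The 27 lists were chosen by their biology: γδ T cell, αβ T cell, pan-T cell, naive and lymph node homing, tissue homing, regulatory T cell, activation, immediate-early, cytokine and chemokine, cytotoxic and NK, type I interferon, interferon-γ, NF-κB, MHC class II, innate receptor, proliferation, glycolysis and hypoxia, oxidative phosphorylation, ribosomal, heat-shock, apoptosis, glucocorticoid-response, myeloid, B cell, plasma cell, erythroid and platelet, and stromal, endothelial and epithelial. Lists needed at least 5 kept genes. The regulatory T cell (4), plasma cell (3), erythroid and platelet (0) and stromal (3) lists had fewer, so 23 were tested. In the time course each list median was set against 10000 random lists of the same size drawn within 20 bins of mean level.

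The pipeline was run on 5 simulated data sets with the same design, in each of which 200 of 13790 probe sets were changed. For γδ against αβ cells 70.1 percent of 2-fold, 99.4 percent of 4-fold and 100 percent of 8-fold changes were recovered, and 8.9 percent of calls were false. For the 48 h change the figures were 23.3, 78.2 and 95.8 percent in αβ cells with 9.1 percent false, and 22.4, 80.3 and 99.7 percent in γδ cells with 8.6 percent false. Infected minus mock recovered 3.9, 32.5 and 62.4 percent in αβ cells with 12.3 percent false, and 3.6, 32.2 and 70.0 percent in γδ cells with 9.5 percent false. The γδ minus αβ change recovered 9.3, 53.7 and 83.3 percent with 3.6 percent false. The false share was thus above the nominal 5 percent in 5 of the 6 comparisons. A list of interferon genes shifted by 0.5 among 6661 genes was called by camera in 5, 5, 5, 4, 4 and 5 of the 5 simulations in the same order, and 1, 1, 1, 2, 0 and 0 of the unshifted lists were called in total. The simulated genes were drawn independently of each other and with equal spread in all calves. These counts therefore do not show how often lists of correlated genes are called falsely.

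Computations used R 4.3.3 with limma 3.58.1, and figures Python 3.11.15 with matplotlib 3.10.9.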

Results

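Gene expression was measured on 18 Affymetrix bovine arrays in T cells sorted from the lymphatic fluid of 3 calves. Calves 112 and 162 were infected with Salmonella Typhimurium, a cause of enterocolitis, and calf 156 was mock infected. The cells had been parted by a γδ T cell antibody into a γδ fraction and an αβ fraction, with 9 arrays of each. Every calf was sampled at 0 and 48 h, and calf 112 also at 6, 24 and 72 h. Precision was limited by the number of calves: 3 for the difference between the cell types, 2 for the change after infection and 1 for the mock infection. Of 24128 probe sets, 13790 were kept as expressed, and 8675 of these carried 1 gene symbol.

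The arrays of calf 112 stood apart from those of the other calves. Across the kept probe sets, arrays of calves 156 and 162 correlated with each other at r of 0.923 to 0.977 and those of calf 112 with each other at 0.824 to 0.929, while pairs joining calf 112 to another calf gave 0.597 to 0.724. Calf 112 had been processed with TRIzol and 2 cycles of amplification, the other calves with a column kit and 1 cycle. On the GAPDH control probe sets the log2 ratio of the 3' to the 5' end was 5.68 to 8.16 in calf 112 and −0.22 to 0.10 in the others. All differences below were taken within each calf before calves were compared.

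The first question was whether the sorted fractions carried the transcripts of their cell type. TCRA, the α chain of the T cell receptor, averaged 13.83 (SD 0.26, 9 arrays) in αβ arrays and 11.58 (SD 0.73) in γδ arrays on the log2 scale. The scavenger receptors CD163L1 and WC1.3, surface molecules of bovine γδ T cells, averaged 11.99 (SD 0.69) and 11.25 (SD 0.94) in γδ arrays against 6.80 (SD 0.76) and 7.30 (SD 0.76) in αβ arrays, and were higher in γδ cells in all 9 pairs. The T cell receptor signalling chains CD3D, CD3E and CD3G were high in both fractions: 12.89, 13.25 and 12.23 in αβ arrays, 13.35, 13.63 and 12.79 in γδ arrays. The probe sets named for the receptor β chain (LOC509513; 14.05 and 14.08) and for the γ chain (TARP; 9.12 and 9.15) had nearly the same level in both. CD4 was low in both (7.60 and 7.43).

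Both fractions also carried transcripts of B cells. The immunoglobulin genes IGHM (15.85 in αβ, 15.31 in γδ arrays) and JCHAIN (13.97 and 12.88) were bright, and MS4A1, the B cell surface protein CD20, averaged 12.94 and 10.28. The median of the B cell list ran from 7.99 to 11.2 over the 18 arrays and that of the plasma cell list from 7.85 to 10.5. The myeloid list ran from 5.96 to 7.29, the cytotoxic and NK list from 6.87 to 8.995, the erythroid and platelet list from 5.40 to 6.73 and the stromal, endothelial and epithelial list from 5.82 to 6.96; levels of different probe sets do not rank cell types. The monocyte receptor CD14 (6.07 in both) and the haemoglobin chain HBB (6.03 and 6.43) fell below the expression threshold. The phagocyte gene CD68 was 7.70 in both, the neutrophil gene S100A8 8.20 (SD 2.03) and 7.79 (SD 2.09), the cytotoxic granule gene GNLY 12.05 and 11.48, the NK receptor gene KLRK1 7.74 and 7.70, and the collagen gene COL1A1 7.09 and 6.95. S100A8 was uneven: in calf 162 it was at 10.39 and 12.44 in αβ and at 7.95 and 13.13 in γδ arrays at 0 and 48 h.

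**Figure D1:**
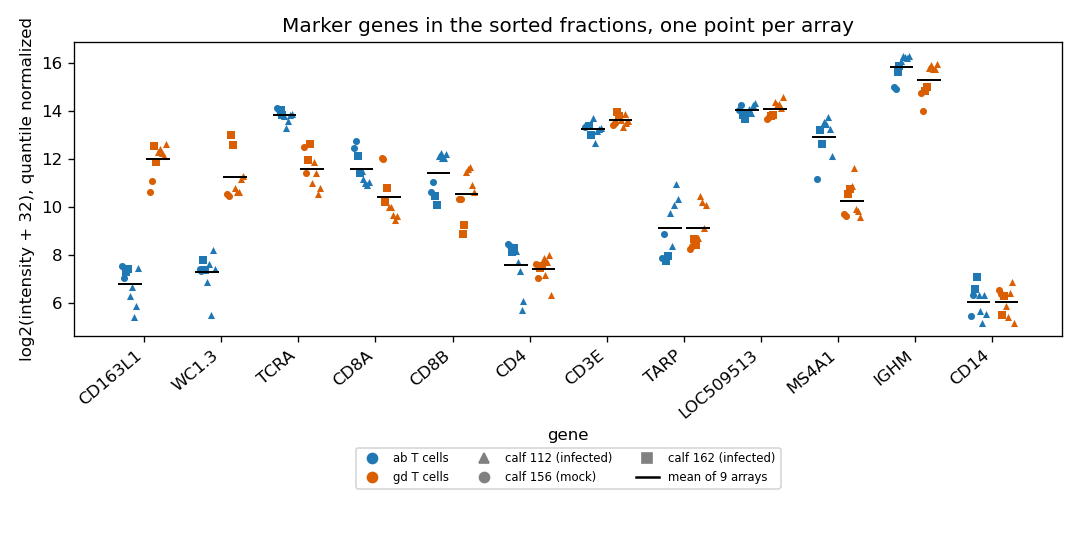
Log2 levels of marker genes in the αβ (ab) and γδ (gd) arrays, 1 point per array. The bar is the mean of 9 arrays.

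Most calls came from the comparison of γδ with αβ T cells. It asked which transcripts differed between the cell types in all 3 calves, each calf entering as 1 mean over its 0 and 48 h differences. BLK, a Src-family kinase, was 39.0-fold higher in γδ cells (log2 5.29, SD 0.38, n = 3 calves, adjusted p = 7.83e-06). CD163L1 was 28.5-fold higher (4.83, SD 1.29, adjusted p = 0.00124) and WC1.3 15.1-fold higher (3.92, SD 1.12, adjusted p = 0.00186). TCRA was 4.82-fold lower (−2.27, SD 0.71, adjusted p = 0.00278), and the B cell gene MS4A1 6.12-fold lower (−2.61, SD 0.39, adjusted p = 0.000434). In αβ arrays CD163L1 and WC1.3 averaged percentiles 39.7 and 50.9, under the expression floor at percentile 60 (log2 8.005), so that their folds are lower bounds.

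In all, limma called 517 of 13790 probe sets, 269 higher and 248 lower in γδ cells. Of these, 408 differed at least 2-fold, and all 517 had the same sign in the 3 calves. They covered 274 gene symbols, and 214 of the probe sets had no single symbol. ENPP1, which hydrolyses extracellular nucleotides, was 4.29 higher (SD 0.56), the oxygen-binding globin CYGB 3.66 (SD 1.24), the chemokine CXCL12 3.49 (SD 0.33) and the calpain protease subunit CAPN2 3.44 (SD 1.003). The genes LOC505306 (5.01, SD 1.11), LOC100335205 (4.78, SD 0.81) and LOC786796 (4.57, SD 0.83) were also among the 10 largest named rises. Besides TCRA and MS4A1, the largest named falls were DAPL1 (−2.73, SD 0.52), the transcription regulator ID2 (−2.45, SD 0.51), the calcium pump ATP2B1 (−2.43, SD 1.29) and POU2AF1, a B cell coactivator (−2.29, SD 0.21). The CDC42 exchange factor FGD2 (−2.23, SD 1.199), the costimulatory receptor CD40 (−2.16, SD 1.10), the phagocyte oxidase subunit CYBB (−2.13, SD 1.18) and the transcription factor IRF5 (−2.13, SD 0.94) were lower as well. From 0 to 48 h CD40, CYBB and MS4A1 moved by 2.36, 1.74 and 2.09 in mock αβ cells, and by 0.39, −1.14 and −0.27 in those of calf 112. A share of B cell RNA in these differences between the fractions was not tested. On their lower side 9 of the 10 highest and 4 of the 10 lowest named genes lay under the floor, which makes those sizes lower bounds too. Without calf 162 the count was 341. Across probe sets the difference correlated between calves at r of 0.41, 0.48 and 0.52.

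**Figure D2:**
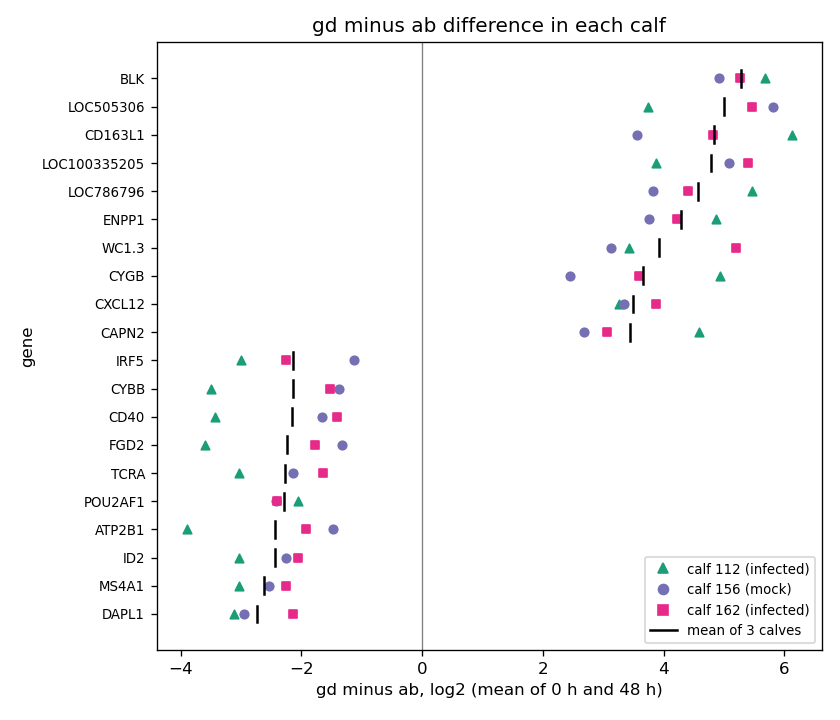
γδ (gd) minus αβ (ab) difference in each of the 3 calves for the 20 named genes of this comparison. The bar is the mean of the calves.

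Gene lists differed between the sorted fractions in lineage, antigen-presentation, B cell and immediate-early genes. Of the 7 measured genes of the γδ T cell list 5 were higher and 0 lower (6 and 0 adjusted over the list alone), among them BLK and the transcription regulator ID3 (2.11, SD 0.28); the list median was 2.11 (adjusted p = 3.85e-08; adjusted p = 0.280 with an estimated correlation). Of the 9 genes of the αβ T cell list 5 were lower and 0 higher (7 and 0 over the list alone), among them the adhesion receptor CD2 (−1.65, SD 0.47) and the coreceptor chains CD8A (−1.11, SD 0.47) and CD8B (−0.88, SD 0.37). Its median was −1.12 (adjusted p = 1.5e-07; adjusted p = 0.280 with an estimated correlation).

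Antigen-presentation genes and most B cell genes were lower in the γδ fraction. As both fractions carried B cell transcripts, these differences cannot be assigned to the T cells themselves. In the MHC class II list 6 of 8 genes were lower and 0 higher, the same counts as over the list alone: BOLA-DRA (−1.71, SD 0.61), BOLA-DQA2 (−2.01, SD 0.73), BOLA-DRB3 (−1.03, SD 0.20) and BOLA-DMB (−0.95, SD 0.43). The list median was −1.14 (adjusted p = 4.13e-08; adjusted p = 0.360 with an estimated correlation). In the B cell list 5 of 6 were lower and 0 higher (5 lower and 1 higher over the list alone, the higher one being the B cell receptor chain CD79A at 0.40, SD 0.24), including IGHM (−0.61, SD 0.23) and the transcription factor SPIB (−1.83, SD 0.48), with a median of −1.80 (adjusted p = 3.18e-06; adjusted p = 0.280 with an estimated correlation). In the myeloid list 2 of 9 were lower, the lysosomal protease LGMN (−0.91, SD 0.53) and CYBB, and 0 higher (4 and 0 over the list alone; median −0.56, adjusted p = 0.00240; adjusted p = 0.360 with an estimated correlation).

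Immediate-early genes, which respond within minutes to a stimulus, were also lower in γδ cells. Of 15 measured, 6 were lower and 0 higher (11 and 0 over the list alone): the AP-1 subunits FOS (−1.62, SD 0.37) and JUNB (−1.50, SD 0.74), the mRNA-decay factor ZFP36 (−0.998, SD 0.22) and the chemokine receptor CXCR4 (−1.44, SD 0.52) were among them. The list median was −0.998 (adjusted p = 3.18e-06; adjusted p = 0.360 with an estimated correlation). The activation list went both ways, with the early activation antigen CD69 lower (−1.56, SD 0.26) and the interleukin receptor chain IL2RA higher (1.67, SD 0.77); 1 of 11 genes passed each way (1 higher and 3 lower over the list alone), and the median was −0.35 (adjusted p = 0.0129; adjusted p = 0.360 with an estimated correlation). In the naive and lymph node homing list 1 of 5 was lower, the transcription factor LEF1 (−1.30, SD 0.33; 1 higher and 3 lower over the list alone), with a median of −0.47 (adjusted p = 0.0455; adjusted p = 0.636 with an estimated correlation). The innate receptor list had a median of −0.23 with 0 of its 9 genes passing, over all genes or alone (adjusted p = 0.0342; adjusted p = 0.360 with an estimated correlation). The adjusted p of the 14 other lists ran from 0.0882 to 0.870, among them the pan-T cell (median 0.28), tissue homing (−0.03), cytokine and chemokine (−0.56), cytotoxic and NK (0.62), glycolysis and hypoxia (−0.02), oxidative phosphorylation (0.02) and ribosomal (−0.03) lists.

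The next comparison asked what changed between 0 and 48 h in the αβ T cells of the 2 infected calves. As groups, interferon-γ, type I interferon and activation genes rose, and immediate-early and MHC class II genes fell, under the preset gene correlation. All 13 interferon-γ genes had a positive mean (median 0.43, adjusted p = 0.0131), among them the immunoproteasome subunit PSMB9 (0.49, SE 0.20) and the peptide transporter TAP2 (0.24, SE 0.17). The SE values here and below are the moderated ones of limma and do not measure the spread between the 2 calves alone. Of 29 type I interferon genes 23 had a positive mean (median 0.26, adjusted p = 0.0341), with the ubiquitin ligase TRIM25 at 0.89 (SE 0.22) and the membrane protein IFITM1 at 0.41 (SE 0.23). Of 15 immediate-early genes 14 had a negative mean (median −0.79, adjusted p = 0.0131). For all 5 lists adjusted p = 0.702 with an estimated correlation.

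No single probe set passed in this comparison. limma called 0 of 13790, with 920 at an unadjusted p under 0.05 where 689.5 were to be expected by chance, and a smallest adjusted p of 0.226. The MHC class II list had a median of −0.34 (adjusted p = 0.0440; BOLA-DRA −0.64, SE 0.20) and the activation list one of 0.29 (adjusted p = 0.0341; the growth regulator MYC 0.84, SE 0.20), both with adjusted p = 0.702 with an estimated correlation. Adjusted over the list alone, 1 activation gene was higher and 0 genes of the other 4 called lists passed. The immediate-early median was −1.65 in calf 112, 0.09 in calf 162 and −0.25 in the mock calf. The other 18 lists had adjusted p from 0.0694 to 0.913.

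Probe sets that were at least 2-fold apart in both infected calves and not in the mock calf were counted next, without a test. In αβ cells 62 were higher and 57 lower, where independence between calves gave 24.7 and 35.2. The mock calf shared the change in 5 and 3 further probe sets. For calf 112 with the mock calf and not calf 162 the counts were 48 and 33 (34.3 and 31.0 under independence), and for calf 162 with the mock calf and not calf 112 they were 11 and 9 (5.34 and 4.14). Without calf 112 the counts were 228 and 261. Calf 112 alone had 1429 probe sets higher and 1810 lower, calf 162 had 244 and 273, and the mock calf 337 and 241.

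Among the named genes of that kind in αβ cells, the cochaperone FKBP4 was 1.83 higher on average (SE 0.27, adjusted p = 0.345; 2.15 in calf 112, 1.51 in calf 162, 0.62 in the mock calf). UBTD1, a ubiquitin-domain protein, was at 2.89 (SE 0.59; 3.597, 2.18 and −0.39 in the same order) and the inhibitory receptor PDCD1 at 2.13 (2.05, 2.20 and 0.25). The stress-induced ZFAND2A was at 1.91 (mock 0.21), ABHD14A at 1.61 (mock −0.19) and PACSIN3 at 1.54 (mock −1.75). On the negative side stood TSPY (−2.47; mock 0.36), ECHDC2 (−1.90; mock 0.56), CLIP2 (−1.84; mock 1.40), SSPO (−1.55; mock 0.41) and the chemokine CXCL2 (−1.50; mock 0.40). The AP-1 subunit JUN had −1.76 on a dim probe set (−2.03 in calf 112 and −1.49 in calf 162), but its brightest probe set had −1.65 in calf 112 and 0.07 in calf 162. The adjusted p of these genes other than FKBP4 was 0.728, and the lower side of all 11 lay under the expression floor in at least 1 infected calf.

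The same question in the γδ T cells of the infected calves gave group changes in interferon, stress and activation genes. The type I interferon list rose (median 0.33, adjusted p = 0.000359), as did the interferon-γ list (0.41, adjusted p = 9.8e-05), whose TAP2 was at 0.26 (SE 0.18) and proteasome activator PSME1 at 0.33 (SE 0.18). The heat-shock list rose (0.36, adjusted p = 0.000152), with the chaperones HSPB1 at 0.95 (SE 0.20) and HSP90AA1 at 0.46 (SE 0.19). The glucocorticoid-response list rose (0.36, adjusted p = 0.0209), with the stress gene DDIT4 at 1.66 (SE 0.30), as did the myeloid list (0.59, adjusted p = 0.0212) and the activation list (0.23, adjusted p = 0.0307; MYC 1.09, SE 0.22). For all 6 lists adjusted p = 0.960 with an estimated correlation. The myeloid median was −0.15 in calf 112 and 0.55 in calf 162, with its neutrophil gene S100A8 at −0.30 and 5.18, and the activation median was 0.01 and 0.46.

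Again 0 of 13790 probe sets passed in limma, with a smallest adjusted p of 0.809. At an unadjusted p under 0.05 stood 619, where 689.5 were to be expected by chance. Adjusted over the list alone, 3 heat-shock genes, 0 type I interferon genes and 1 gene each of the interferon-γ, myeloid, glucocorticoid-response and activation lists were higher. The other 17 lists had adjusted p from 0.228 to 0.899. At least 2-fold in both infected calves and not in the mock calf were 43 probe sets higher and 50 lower (23.0 and 33.4 under independence), with 2 and 5 shared by the mock calf. Calf 112 with the mock calf gave 13 and 40 (8.30 and 28.1), and calf 162 with the mock calf 10 and 25 (1.78 and 5.32). Without calf 112 the counts were 259 and 282. Calf 112 alone had 1179 higher and 1504 lower (1300 and 1134 on the deposited scale, the opposite balance), calf 162 had 271 and 312, and the mock calf 99 and 264.

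In γδ cells the neutrophil-type calcium-binding gene S100A12 was at 3.48 (SE 0.55, adjusted p = 0.809), from 2.45 in calf 112, 4.51 in calf 162 and −0.34 in the mock calf; the value in calf 112 started from 5.30, far under the expression floor. Of the 12 named genes of this comparison 11 lay under the floor on their lower side in an infected calf, DDIT4 being the exception. DDIT4 was at 2.12, 1.205 and −0.37 in the same calves, and the glucocorticoid-induced immunophilin FKBP5 at 1.38, 1.203 and 0.02. NXPH3 (1.74; mock −0.35), the G protein subunit GNA11 (1.49; mock −0.51) and the actin regulator WASL (1.49; mock −1.14) followed. On the negative side were the guidance factor SLIT3 (−2.58; mock 0.00), MYOZ1 (−2.17; mock 0.22), ATP13A2 (−1.77; mock −0.70), CRTC1 (−1.72; mock 0.22), the MAP kinase kinase MAP2K2 (−1.58; mock −0.38) and MPZL2 (−1.38; mock 0.21). The adjusted p was 0.809 for DDIT4 and 0.953 for the other 10.

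**Figure D3:**
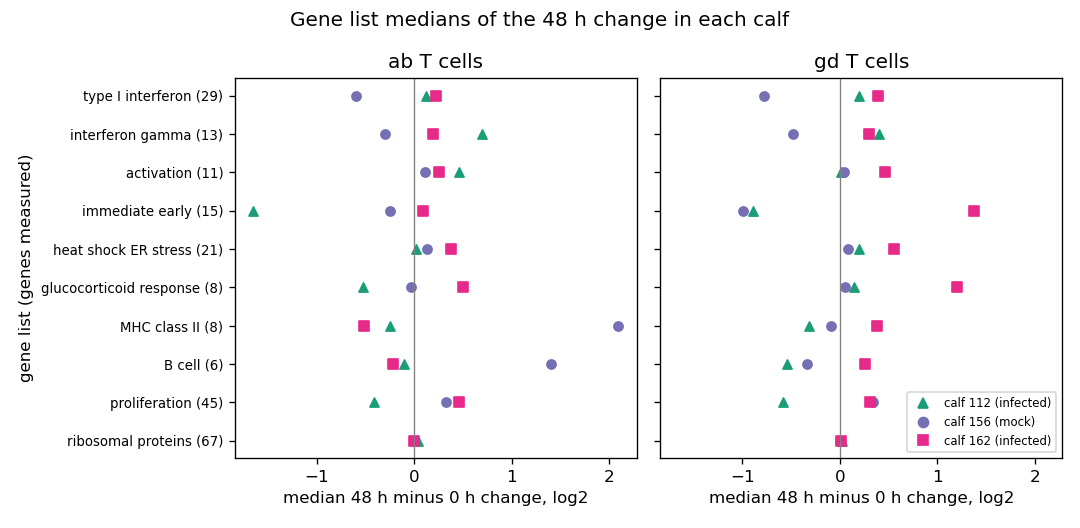
Median change of 10 gene lists from 0 to 48 h in each calf, for αβ (ab) and γδ (gd) T cells. The number of measured genes stands beside each list.

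Subtracting the mock calf asked whether the changes differed from those without infection, with 1 mock calf to set against 2 infected calves. Small list p values at the preset correlation do not speak for infection here, since a shift in the 1 mock calf alone can give them. In both cell types the probe sets at an unadjusted p under 0.05 were fewer than the 689.5 to be expected by chance. In αβ cells, MHC class II genes fell relative to the mock calf (median −2.56, adjusted p = 3.42e-10), as did B cell genes (−1.36, adjusted p = 3.03e-05). BOLA-DRA was at −2.79 (SE 0.34), BOLA-DQA2 at −2.67 (SE 0.37), BOLA-DRB3 at −2.57 (SE 0.35) and MS4A1 at −2.52 (SE 0.37), each with adjusted p = 0.165, and the B cell receptor chain CD79A at −2.70 (SE 0.46, adjusted p = 0.205). The change sat in the mock calf: the MHC class II median was 2.09 there, −0.25 in calf 112 and −0.51 in calf 162, and the B cell median was 1.40, −0.11 and −0.22. Its 0 h αβ array was the low one: the median MHC class II level was 8.59 there, against 9.83 to 10.69 on the other αβ arrays. Type I interferon genes (0.96, adjusted p = 1.35e-09; TRIM25 1.298, SE 0.38) and interferon-γ genes (0.61, adjusted p = 4.45e-05; PSMB9 0.34, SE 0.35) rose relative to the mock calf. For all 4 lists adjusted p = 0.839 with an estimated correlation. limma called 0 probe sets (409 at an unadjusted p under 0.05, smallest adjusted p = 0.165), and over the list alone 7 MHC class II and 2 B cell genes were lower and 0 interferon genes passed. The other 19 lists had adjusted p from 0.0731 to 0.869.

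Of the genes singled out by fold in αβ cells, UBTD1 was at 3.28 (SE 1.02) relative to the mock calf, PACSIN3 at 3.28 (SE 1.23) and CLIP2 at −3.24 (SE 0.88, adjusted p = 0.982). FKBP4 was at 1.21 (SE 0.47), PDCD1 at 1.88 (SE 1.10), TSPY at −2.83 (SE 1.21) and ECHDC2 at −2.46 (SE 1.25). All of these but FKBP4 reached under the expression floor in an infected calf.

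In γδ cells the interferon lists differed most from the mock calf. Type I interferon genes rose relative to it (median 1.12, adjusted p = 8.16e-22; the interferon-induced PARP12 1.09, SE 0.34), as did interferon-γ genes (1.10, adjusted p = 1.06e-12; TAP2 0.74, SE 0.31). The type I median was 0.19 in calf 112, 0.39 in calf 162 and −0.77 in the mock calf. Immediate-early genes (0.70, adjusted p = 9.58e-05; FOS 2.26, SE 1.43), glucocorticoid-response genes (0.44, adjusted p = 0.0113; DDIT4 2.03, SE 0.52), the αβ T cell list (0.43, adjusted p = 0.0113; TCRA 1.19, SE 0.46) and the apoptosis list (0.28, adjusted p = 0.0382; the survival factor MCL1 1.93, SE 0.49) rose relative to the mock calf. So did heat-shock genes (0.24, adjusted p = 0.00275), activation genes (0.18, adjusted p = 0.0113; CD69 3.25, SE 0.92; MYC 1.74, SE 0.38) and NF-κB genes (0.17, adjusted p = 0.0288; the inhibitor NFKBIA 0.17, SE 0.83). Proliferation genes fell relative to it (−0.56, adjusted p = 0.000422; the replication helicase subunit MCM7 −1.11, SE 0.42). For all 10 lists adjusted p = 0.744 with an estimated correlation. The αβ T cell median was −0.47 in calf 112 and −0.49 in the mock calf, the activation median 0.01 and 0.05 and the immediate-early median −0.89 and −0.99, so that these 3 differences rested on calf 162 (0.39, 0.46 and 1.37). The glucocorticoid-response median was 0.15 in calf 112, 1.204 in calf 162 and 0.06 in the mock calf, and the proliferation median −0.58, 0.31 and 0.34, a fall in calf 112 alone.

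Over the list alone 7 type I interferon, 4 interferon-γ and 2 activation genes were higher, with 1 each of the immediate-early, NF-κB, apoptosis and glucocorticoid-response lists and 0 of the other 3 called lists. The remaining 13 lists had adjusted p from 0.117 to 0.828. limma called 5 probe sets (246 at an unadjusted p under 0.05), each with adjusted p = 0.0464, and 0 on the deposited scale, median-centred, with a constant of 1, without a filter or without the variance trend. The named one, LOC524810, an immunoglobulin heavy-chain gene, was 2.53 higher than in the mock calf (SE 0.32), with −0.12 in calf 112, 0.26 in calf 162 and −2.46 in the mock calf. The other 4 had no single gene symbol and were 3.99, 3.53, 3.34 and 2.85 higher than in the mock calf. The 246 probe sets at an unadjusted p under 0.05 were well under the 689.5 to be expected by chance.

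The last tested comparison asked whether γδ and αβ cells of the infected calves changed differently. RGS1, a regulator of G protein signalling, rose in γδ relative to αβ cells by 2.25 (SE 0.31, adjusted p = 0.00171), by 2.88 in calf 112 and 1.63 in calf 162, against −0.88 in the mock calf. In calf 112 it was −2.59 in αβ and 0.29 in γδ cells, in calf 162 it was 1.005 and 2.63. Of the 15 immediate-early genes 14 had a positive mean, with a list median of 0.97 and adjusted p = 2.1e-06 (adjusted p = 0.876 with an estimated correlation). The list median was 0.39 in calf 112, 1.08 in calf 162 and −0.57 in the mock calf. FOS at 0.98 (moderated SE 0.34) and JUN at 0.92 (moderated SE 0.30) were carried by calf 162. They were at −0.22 and 0.07 in calf 112 and at 2.18 and 1.77 in calf 162, a wider spread than these SE values convey. RGS1 was the 1 call of limma, but 0 were called with a constant of 1 or without the variance trend. At an unadjusted p under 0.05 stood 766 probe sets, where 689.5 were to be expected by chance. Over the list alone 6 immediate-early genes were higher. The other 22 lists had adjusted p from 0.0994 to 0.912.

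Named genes at least 2-fold apart in both infected calves and not in the mock calf included S100A12 (2.95, SE 0.66) and UBTD1 (−3.64, SE 0.78), each with adjusted p = 0.3004. The serine-degrading enzyme SDS was at 2.67 (SE 0.84), WASL at 2.30 (SE 0.91) and NPFF at 2.03 (SE 0.91). ATRN (−2.68, SE 0.87), SLIT3 (−2.59, SE 0.84), PDCD1 (−2.25), the phosphatase subunit PPP1R16A (−2.21, SE 0.66) and ABLIM3 (−2.18, SE 0.81) lay on the other side. JUN on another probe set than those named above was at 1.86 (SE 0.49). All 11 of these genes had a lower side under the expression floor in an infected calf, so their sizes are uncertain.

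Within each calf the αβ and γδ changes correlated across probe sets at r of 0.10 in calf 112, 0.26 in the mock calf and 0.41 in calf 162. Between calves the αβ changes correlated at 0.096 for the infected calves and at −0.037 and −0.042 for each of them with the mock calf. The γδ changes gave 0.011 for the infected calves and −0.068 and 0.086 with the mock calf.

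The time course of calf 112 asked how both cell types of 1 infected calf moved from 0 h on, with 1 array per point and no test. Immediate-early genes were below all 10000 random lists of equal size and level in αβ cells at 6, 24, 48 and 72 h (medians −1.49, −0.67, −1.65 and −1.03) and in γδ cells at 6, 24 and 48 h (−0.79, −0.60 and −0.89), but not at 72 h (−0.14). Interferon-γ genes stood at 0.12, 0.09, 0.70 and 0.69 in αβ cells and at 0.11, 0.03, 0.40 and 0.82 in γδ cells, at percentiles 100 and 99.76 of random lists in αβ and 99.48 and 100 in γδ cells at 48 and 72 h. Proliferation genes stood at 0.66, 0.45, −0.42 and 0.22 in αβ cells and at 0.21, −0.09, −0.58 and −0.24 in γδ cells. The heat-shock list was at 0.33 in αβ and 0.28 in γδ cells at 6 h, the oxidative phosphorylation list at 0.39 and 0.35 in αβ cells at 6 and 24 h, and the apoptosis list at 0.65 and 0.66 in αβ cells at 6 and 48 h and at 0.34 and 0.44 in γδ cells at 24 and 72 h. In αβ cells MHC class II genes swung between arrays, at −0.46, 0.37, −0.25 and −0.94 at 6, 24, 48 and 72 h (percentiles 0.7, 96.7, 13.78 and 0.11). B cell genes were at −0.64 (percentile 2.08) in αβ cells at 72 h. In γδ cells at 72 h MHC class II genes went the other way, at 0.41 (percentile 97.87), with B cell genes at −0.32 (percentile 5.04). The points of a cell type share its single 0 h array, so they are not independent, and a high value on that array lowers all of them alike. The type I interferon list was outside the central 95 percent of random lists at 0 of the 8 points.

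**Figure D4:**
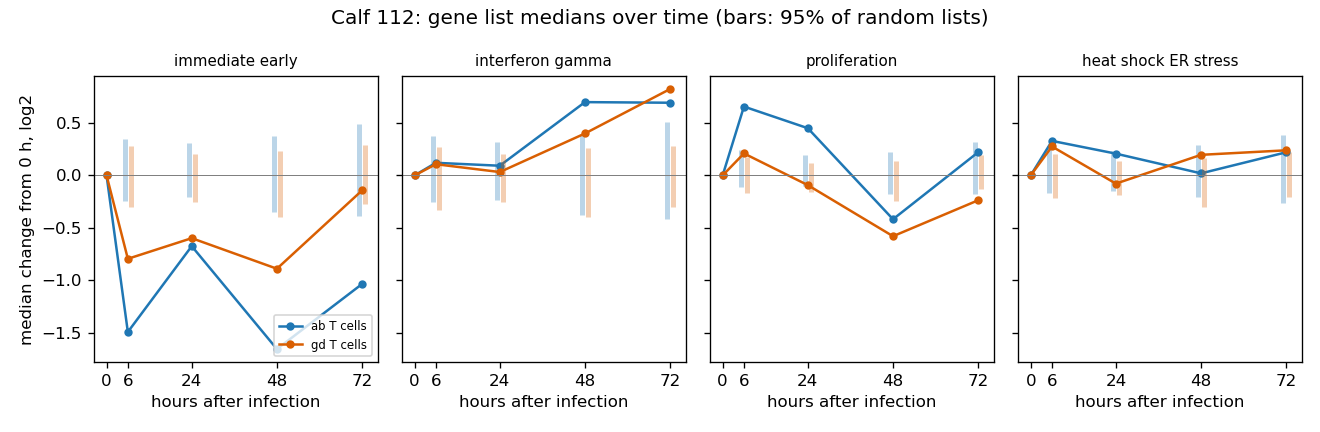
Median change from 0 h of 4 gene lists in αβ (ab) and γδ (gd) T cells of calf 112, with 1 array per point. Bars span 95 percent of random lists.

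At least 2-fold from 0 h were, in αβ cells, 1222 probe sets higher and 1257 lower at 6 h, 1140 and 1097 at 24 h, 1429 and 1810 at 48 h, and 1701 and 2194 at 72 h. In γδ cells the counts were 1127 and 1405 at 6 h, 942 and 957 at 24 h, 1179 and 1504 at 48 h, and 1031 and 1026 at 72 h. On the deposited scale the γδ counts were 1256 higher and 1041 lower at 6 h, 895 and 773 at 24 h, 1300 and 1134 at 48 h, and 947 and 988 at 72 h, so that the balance of rises and falls depended on the scaling. Higher in both cell types were 174, 169, 235 and 236 at the 4 times (99.9, 77.9, 122 and 127 under independence) and lower in both 242, 154, 335 and 230 (128, 76.1, 197 and 163). At 48 h the transcription factor ATF3 was at −3.64 in αβ and −3.70 in γδ cells, the MAP kinase phosphatase DUSP1 at −3.26 and −2.73 and PAQR6 at −2.99 and −3.14, while the lipid kinase PI4K2A was at 3.27 and 2.85 and the tight-junction gene CLDN19 at 2.82 and 2.79. At 6 h the lysozyme gene LYZ2 was at 2.98 and 2.41 and the mitochondrial ribosomal gene MRPL38 at −3.11 and −3.06. At 24 h CLGN (2.81 and 2.77) and ISOC2 (2.72 and 2.48) were higher and the death-receptor adaptor FADD (−2.80 and −2.77) lower. At 72 h CHCHD6 was at 2.93 and 2.41 and the growth factor FGF1 at −3.01 and −3.39. Of these 12 genes all but DUSP1 lay under the expression floor on their lower side in both cell types, so their sizes rest on single arrays near background.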

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

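Among the tests of explanations in this part, only the regrouping of calves was planned before its outcome was known. The others were chosen after the result had been seen. The estimated correlation and the processing settings under which calls were lost had been planned. The results gathered here drew attention because the contrast between infected and mock calves, or between the changes of the cell types, passed its own test while resting on 1 or 2 calves per side. The gene lists among them passed only at the preset correlation, with adjusted p = 0.839 for infected minus mock αβ cells, 0.744 for γδ cells and 0.876 for the difference between cell types with an estimated correlation.

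Regrouping the arrays gave too few arrangements to judge any count by. With the 6 calf means of γδ and αβ cells taken as unpaired, 1 of 10 arrangements, the real one, gave as many calls as the real count of 1, and the highest other count was 0. With the cell types exchanged within calves, 1 of 4 arrangements gave as many as the real 517, and the highest other count was 0.

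MHC class II genes (−2.56) and B cell genes (−1.36) fell in infected αβ cells relative to the mock calf, where the MHC class II median was 2.09 in the mock calf. The mock αβ array at 0 h stood apart in level. Its median MHC class II level was 8.59, within the 8.55 to 9.07 of the γδ arrays, and the other αβ arrays ran from 9.83 to 10.69. Its B cell median of 9.22 was the lowest of the αβ arrays. The contrast therefore rests on that 1 array. RNA of B cells in the αβ fraction stayed open: the B cell list had a median change of 1.40 there, with MS4A1 at 2.09 and CD79A at 2.00, and of −0.34 in the γδ cells of the mock calf. These genes are part of the pattern itself. The rise in IGHM of the same list that was set down for this explanation was absent, with 15.02 and 14.92 on the 2 arrays. IGHM had room to rise, being at 15.65 and 15.86 in the αβ arrays of calf 162. In mock αβ cells the immunoglobulin gene JCHAIN moved by −0.25. Induction of MHC class II in T cells without B cell RNA would have left the B cell list near 0, and it was at 1.40. As that rise is part of the pattern, it was known beforehand and no conclusion is drawn from it. The normalization was not the source, since the smallest MHC class II median over 3 scalings was 1.81.

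Immediate-early genes rose in γδ cells relative to the mock calf (0.70) and relative to αβ cells (0.97), and RGS1, one of them, was higher in the latter by 2.25 (not called with a constant of 1 or without the variance trend). Infection as the whole cause was neither shown nor excluded for the γδ change: the median was −0.89 in calf 112 (quartiles −2.02 and 0.08) and 1.37 in calf 162 (0.55 and 2.30), each from 1 array per time and under different protocols. Handling of the cells before lysis was not measured and stayed open. The mock calf moved by −0.99 with 14 of 15 genes below 0. As that fall is part of the pattern, it was known beforehand and no conclusion about handling is drawn from it. The normalization was not the source of the rise in calf 162, whose smallest median over 3 scalings was 1.22, but on the same γδ arrays the neutrophil genes S100A8, S100A9 and S100A12 were at 5.18, 4.16 and 4.51, and a part of neutrophil RNA was not tested. For the difference from αβ cells infection stayed open and untested, as both infected calves lay on the other side of the mock calf (0.39, 1.08 and −0.57 for the list, 2.88, 1.63 and −0.88 for RGS1 in calves 112, 162 and the mock calf).

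Type I interferon genes (1.12) and interferon-γ genes (1.10) rose in γδ cells relative to the mock calf, and so did both lists in αβ cells (0.96 and 0.61). The protocol of calf 112 was set aside for the type I genes in γδ cells, because calf 162, processed like the mock calf, exceeded it by a median of 1.15. A higher starting level in the mock calf is consistent with its median excess over calf 162 of 1.06 at 0 h, against −0.13 at 48 h. In αβ cells the excess was 1.19 at 0 h and 0.37 at 48 h. For the type I genes in γδ cells the normalization was not the source, as their smallest median over 3 scalings was 0.93. The interferon-γ genes and the αβ cells were not examined in that way. An effect of infection itself was not separable from the state of 1 mock calf.

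The immunoglobulin gene LOC524810 (2.53) rose in γδ cells relative to the mock calf, where it was at −2.46, and was not called on the deposited scale, median-centred, with a constant of 1, without a filter or without the variance trend. The same losses held for 4 probe sets without a single gene symbol (3.53, 2.85, 3.99 and 3.34), whose mock values were −2.22, −2.59, −2.37 and −2.56. The αβ T cell list (0.43) was at −0.47 in calf 112, 0.39 in calf 162 and −0.49 in the mock calf, so the rise rested on calf 162. The activation list (0.18) rested on calf 162 as well (0.46, beside 0.01 in calf 112 and 0.05 in the mock calf; CD69 2.86, −0.37 and −2.00). Glucocorticoid-response genes (0.44) were at 1.204 in calf 162 and 0.15 in calf 112, beside 0.06 in the mock calf. Proliferation genes (−0.56) were at −0.58 in calf 112 and 0.31 in calf 162, beside 0.34 in the mock calf. Heat-shock genes (0.24) were at 0.56 in calf 162 and 0.20 in calf 112, beside 0.09 in the mock calf. The NF-κB list (0.17) was at 0.08, 0.17 and −0.05 and the apoptosis list (0.28) at 0.17, 0.23 and −0.11 in calves 112, 162 and the mock calf.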

How the results depend on the processing

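The settings that change the filter on calf 112 levels, leave out the 3 rescaled arrays or drop the pairing in the list tests were chosen after the data had been seen, and the others before. With 3 calves, the infected minus mock comparisons had no fit with 1 calf left out, and the 48 h changes and their difference between cell types had one only without the mock calf. The difference between cell types in change had no unpaired fit. Where a value below departs from the one in the results, the cause was not tested unless it is stated.

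For γδ against αβ cells (517 calls), 264 were called without the variance trend (255 of them among the 517), 207 on 0 h arrays alone (199), 219 on 48 h arrays alone (215), and 1950 (505) when all 9 pairs of arrays were treated as independent, which counts each calf more than once. The fit without the calf as replicate block, that is without pairing, called 1, since differences between calves then entered the error. Leaving out 1 calf gave 341 to 566. Probe sets with a mean in calf 112 above 10, 11 or 12 gave 220, 124 and 59, from fewer probe sets. None of the 38 named and list genes called in this comparison reversed sign under any setting. IRAK4, not called and near 0, ran from −0.10 to 0.036 when 1 calf was left out and turned to 0.12 at 48 h alone and 0.10 over all pairs, and S100A8, not called, to 0.086 at 48 h alone.

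The comparisons over time gave few calls in any setting. For the αβ change (0 calls) there was 1 on the deposited scale, 4 with a constant of 100, 1 without a filter, and 4 and 7 with calf 112 means above 10 and 11. For the γδ change (0 calls) there were 37 with a constant of 100 and 1 with calf 112 means above 12. For infected minus mock in αβ cells (0 calls) there were 7 on the deposited scale, 25 with a constant of 100, 12 without a filter, and 30, 23 and 2 with calf 112 means above 10, 11 and 12.

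For infected minus mock in γδ cells (5 calls) there were 0 on the deposited scale, median-centred, with a constant of 1, without a filter, with a mean filter, without the variance trend, with both cell types in 1 fit, without the 3 rescaled arrays, and with calf 112 means above 11. Without the calf as block or pairing there were also 0. A constant of 100 gave 36, and calf 112 means above 8, 9 and 12 gave 2, 3 and 2. For the difference between cell types in change (1 call, RGS1) there were 0 with a constant of 1, without the variance trend and with calf 112 means above 11 and 12, against 30 with a constant of 100, 28 without a filter and 6 with calf 112 means above 9.

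In the list tests an estimated correlation left 0 lists in each of the 6 comparisons. With 1 or 2 residual degrees of freedom at that setting, this outcome was nearly fixed in advance. For the αβ change 3 lists were called without a filter in place of 5. For the difference between cell types in change, where 1 list was called, 3 were called with the mean over the probe sets of a gene, 3 on the deposited scale, 5 median-centred, 2 with a constant of 100, 4 with a mean filter and 3 without the 3 rescaled arrays. Without the block or pairing, 10, 5, 6, 4 and 11 lists were called in the other comparisons in the order of the results.

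Genes that were not called changed sign under other scalings. Median centring moved the median of all probe sets to −0.12 for the γδ change and −0.14 for infected minus mock in γδ cells, from −0.01 and −0.03. Some genes of the latter moved further than that, such as IFITM1 (0.13 to −0.28) and HSP90AB1 (0.24 to −0.056), and the cause was not tested. In the γδ change TRIM25 turned to −0.070 median-centred and CYBB to 0.032 with a constant of 100. For infected minus mock in γδ cells on the deposited scale CD8A turned to −0.036, IFITM1 to −0.12, BIRC3 to −0.010, HSPA8 to −0.030 and BCL2 to −0.0036. Median-centred, CD8A turned to −0.19, IER2 to −0.083, IFITM1 to −0.28, BIRC3 to −0.16, RELA to −0.051, NFKB1 to −0.093, NFKBIA to −0.041, HSPA8 to −0.18, HSP90AA1 to −0.11, HSP90AB1 to −0.056 and BCL2 to −0.16.

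The counts at least 2-fold in both infected calves and not in the mock calf (62 higher and 57 lower in αβ, 43 and 50 in γδ cells) depended on the treatment of dim probe sets. They were 127, 107, 91 and 111 with a constant of 1, 15, 10, 8 and 6 with a constant of 100, 154, 159, 146 and 157 without a filter, and 30, 33, 17 and 28 with a mean filter. At 1.5-fold they were 319, 345, 245 and 252, at 3-fold 5, 2, 4 and 6. Leaving out 1 calf gave 67 to 1376, 60 to 1774, 45 to 1164 and 55 to 1459. In the time course a constant of 100 gave 1325, 1141, 1982 and 2595 probe sets at least 2-fold from 0 h in αβ cells at 6, 24, 48 and 72 h, against 2479, 2237, 3239 and 3895. In γδ cells it gave 1362, 899, 1528 and 1033 against 2532, 1899, 2683 and 2057, and a mean filter gave 1251 in γδ cells at 24 h.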

Other observations

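Several genes outside the naming rule stood out in calf 162 and were each chosen after its values were seen. The calprotectin chains S100A8 and S100A9 were at 5.18 and 4.16 at 48 h in its γδ cells, beside −0.30 and −0.23 in calf 112 and −0.27 and 0.11 in the mock calf. In αβ cells of calf 162 they were at 2.05 and 0.85. The phagocyte genes CYBB, CD68 and CST3 were at 0.35, 0.55 and −0.32 in the same γδ cells.

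Some genes that respond to temperature had the same sign in both infected calves and others did not, and each was again chosen after its values were seen. The chaperone HSPH1 was at 1.05 and 2.08 in αβ cells of calves 112 and 162 and at 0.37 and 2.05 in their γδ cells, beside 0.05 and 0.12 in the mock calf. The cochaperone STIP1 was at 1.01 and 1.12 in αβ and at 0.15 and 1.38 in γδ cells, beside −0.09 and 0.28 in the mock calf. The cold-induced RNA-binding genes RBM3 (−1.10 and −1.44 in αβ, −0.72 and −1.29 in γδ cells) and CIRBP (−0.52 and −0.82, −1.30 and −0.74) were negative, with the mock calf at 0.21 and −0.32 for RBM3 and at 0.47 and 0.27 for CIRBP. In αβ cells the chaperones HSPB1 (−0.11 in calf 112 and 1.11 in calf 162) and HSP90AA1 (−0.28 and 0.60) differed in sign. The cytokine-signalling inhibitor CISH was at 1.26 and 1.45 in αβ and at 1.40 and 1.08 in γδ cells, beside −0.05 and −0.19 in the mock calf. The cytotoxic granule gene GNLY went from 10.4 at 0 h to 11.7, 11.5, 12.4 and 13.3 at 6, 24, 48 and 72 h in αβ cells of calf 112, while in its γδ cells it was at 11.03, 11.18, 10.74, 10.65 and 12.36. No cause was tested for these patterns.

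The tests behind the next lines were chosen only after the results had been seen. Between its 0 and 48 h arrays the mock calf also moved, by 1.40 in B cell genes in αβ cells and by −0.99 in immediate-early genes in γδ cells. A second mock calf, sorted and processed in parallel, could show whether such shifts recur without infection. If sorted αβ cells carry a variable share of B cells, then a measure of MS4A1 protein on the sorted cells would vary with the transcript, which was at 2.09 in mock αβ cells between 0 and 48 h.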
